A study of Mus musculus with 6 samples.

How the data were processed

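Per the labels' protocols, RNA bound to Spy3-AGO2 was isolated from a mouse embryonic stem cell line with HaloTag-SpyCatcher3 on HaloLink resin, separated on a gel and purified from a slice of it. Input RNA came from whole lysate. Adapters with randomised bases were ligated to both ends, and libraries were amplified by PCR and sequenced as single-end reads. The 6 libraries form 3 groups of 2, the miRNA, target and input libraries, as their titles state.

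The authors deposited 1 table of raw counts per mature miRNA for each miRNA library, with no normalization. The submitters' processing notes name UMI-tools, cutadapt 2.10, STAR 2.5.2a, Bowtie2 2.4.2, DESeq2 1.36.0, deepTools 3.1.3 and the mm10 genome build, without saying which was used for what. Whether counts were collapsed by molecular identifier, and how reads matching several miRNAs were treated, is not given in the sources used here. PCR duplicates that were not collapsed would make intervals too narrow and test statistics too large. A last row that names no miRNA held 0 counts in both tables and was left out. The deposited peak list gave positions and strand for 3292 peaks of the whole series, and its score column was 0 for every peak, so that peaks could not be ranked or filtered by score. Peak numbers reached 30438, and the listed peaks are 10.8% of that number. The peak caller, its threshold and the use of the input libraries are not given in the sources used here. A longer or shorter list would change every count of genes with peaks. No column of values per sample was left unused.

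From the counts, the share of each mature miRNA in its library total was computed, with a mean and SD over the replicates and a 95% Wilson interval per library. The floor for a count of 0 was set at 3 counts. Depth was 12562727 counts in replicate 1 and 22908172 in replicate 2, where 3 counts are 2.39e-05% and 1.31e-05% of the total. Shares were summed over 16 lists of miRNAs and over families with the same seed. The lists and seeds were fixed before the data were examined. The members of each seed family were assigned after the files were read, from known mature sequences. Arm use was computed for hairpins with at least 100 counts over both arms in each library. Replicates were compared by a chi-square test of homogeneity, Fisher's exact test per miRNA with Benjamini-Hochberg adjustment at 0.05, and correlation across miRNAs of log2(CPM + 1). The spread between the replicates was also estimated with edgeR 4.0.16, whose biological coefficient of variation was 18.1% over 677 miRNAs with at least 10 counts in each library. With 1 group of 2 miRNA libraries and no other values per library, no contrast between groups could be fitted.

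Peaks were assigned by midpoint to gene spans of the NCBI RefSeq annotation of GRCm38.p6, the same assembly as mm10, irrespective of gene strand, since that table gave neither strand nor exons. It held 49997 genes, of which 21900 were protein-coding. Position was measured along the span in the direction of the peak strand, for peaks within exactly 1 protein-coding nuclear gene. The mean position was compared with 10000 sets of uniform random positions. Coordinates are counted from 1. The share of peaks per location has an exact Clopper-Pearson interval. Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, matplotlib 3.10.9 and R 4.3.3 were used.

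The rule for names, fixed before the data were examined, took the 20 miRNAs with the highest mean share and every list member with at least 0.1%, the negative control families, the 10 genes with the most peaks and every listed gene with a peak. Some listed genes are counted in the totals of their lists and are not reported here by name. A further part, the 20 genes with the highest-ranked peak in a 3' untranslated region, was not applied because those regions were not used here. For the same reason the planned tests of seed matches in peaks, of family abundance against seed matches and of positions within 3' untranslated regions were not run, and positions along gene spans replaced the last. Atf2, the noncoding genes and pseudogenes, the mitochondrial genes, the ribosomal protein genes, miR-122-5p, miR-370-3p, miR-199a-5p, miR-199a-3p, miR-199b-3p, the list members under 0.1%, the listed genes with 0 peaks, and Lamp2, Nedd4, Nsd1, Prrc2a, Lmtk2, Tnks2 and Tns3 were named after their values were seen.

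The steps were tested on simulated data. With both libraries drawn from the same shares for 1978 miRNAs, the exact test called 0. Of 100 miRNAs changed 1.2-fold, 69% were recovered, and of 100 changed 2-fold, 100%. These simulated libraries held counting error only, whereas the real ones had a biological coefficient of variation of 18.1%. The simulation therefore does not give the error rate of the exact test on the real libraries. For the position test, a permutation-type test against random sets, 3000 simulated uniform positions gave p = 0.509 and 3000 shifted ones p = 0.0001. All of 500 simulated peaks at gene centres were assigned to their gene. Their placing made this certain, so it checks only that the step ran, not the rule of exactly 1 gene. Alternatives covered DESeq2 1.42.0 size factors and edgeR TMM factors, count minimums, the pseudocount, the seed definition, each replicate alone, overlap in place of the midpoint, and settings chosen after seeing the data, namely position subsets, distance to the downstream end, at least 2 peaks per gene, nuclear chromosomes only, miR-290a-5p left out of the total and of the sums that held it, and hairpins with an arm sharing its sequence with another name left out.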

Results

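The series measured the RNA held by AGO2, the Argonaute protein that carries microRNAs (miRNAs) to their target RNAs, in a mouse embryonic stem cell line of the Spy3-Ago2 genotype. The library names begin with E14, a widely used mouse embryonic stem cell line, and the cells were grown with serum and LIF, a cytokine that keeps such cells undifferentiated. Spy3-AGO2 was pulled down through SpyCatcher3, a protein that binds the Spy3 tag covalently. The 6 libraries comprised 2 miRNA libraries and 2 target libraries from the pull-down, and 2 input libraries from whole lysate. Each miRNA library had a table of raw counts for 1978 mature miRNAs, and a single list of 3292 target peaks stood for the whole series. The miRNA tables held 12562727 counts in replicate 1 and 22908172 counts in replicate 2, a 1.82-fold difference in depth. At least 1 count was recorded for 1064 miRNAs in replicate 1 and for 1114 miRNAs in replicate 2. The labels do not say whether the replicates were separate cultures, so the spread between them may be technical. Values per replicate of the target and input libraries were not analysed here.

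The first question was which miRNAs AGO2 held in these cells. miR-290a-5p, from the miR-290/miR-295 cluster that is characteristic of mouse embryonic stem cells, made up 23.8% ± 0.40 of the miRNA counts (SD, n = 2 here and for every share below). miR-92a-3p of the miR-17-92 cluster followed with 7.24% ± 0.30, and miR-182-5p with 6.36% ± 0.97. miR-19b-3p took 4.74% ± 0.14 and miR-16-5p 4.67% ± 0.62. These 5 miRNAs together held 46.8% ± 0.49 of the counts, and the 20 most abundant miRNAs held 71.2% ± 0.13. The next places were taken by miR-291a-5p with 3.43% ± 0.38, miR-291a-3p with 2.89% ± 0.68, miR-127-3p with 2.61% ± 0.40, miR-295-3p with 2.51% ± 0.18 and miR-292a-5p with 2.34% ± 0.19. miR-292a-3p, miR-19a-3p, miR-124-3p, miR-183-5p and miR-20a-5p lay between 1.00% and 1.42%. miR-27a-3p, miR-294-5p, miR-17-5p, miR-96-5p and miR-26a-5p lay between 0.848% and 0.958%. The lead of miR-290a-5p over miR-92a-3p exceeded the SD of either miRNA. The shares of miR-92a-3p and miR-182-5p differed by less than the SD of miR-182-5p, with 7.45% and 5.67% in replicate 1 but 7.03% and 7.04% in replicate 2, and those of miR-19b-3p and miR-16-5p by less than the SD of miR-16-5p. Of the 19 neighbouring pairs among the 20 most abundant miRNAs, 11 changed order in a replicate, so most of the places are not settled.

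**Figure D1:**
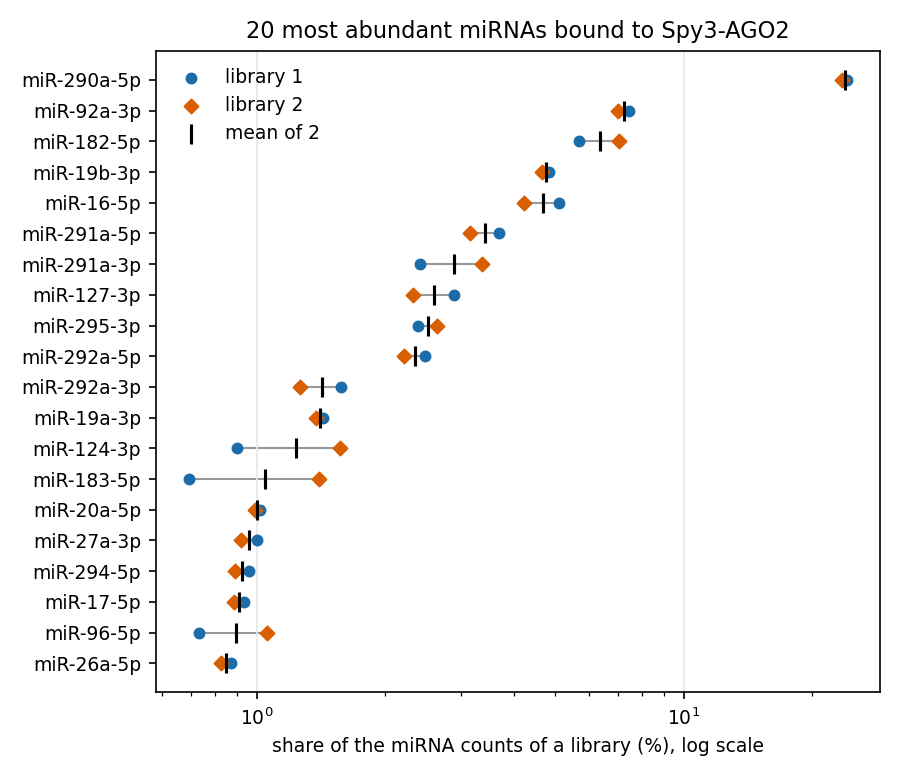
Share of the miRNA counts of a library (percent, log axis) for the 20 most abundant miRNAs bound to Spy3-AGO2, with a circle for replicate 1, a diamond for replicate 2 and a bar for their mean. miR-290a-5p stands at 23.8%, and the widest gaps between the replicates are those of miR-183-5p and miR-124-3p.

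Among the 20 most abundant miRNAs, the ratio between replicates was largest for miR-183-5p, 2.02-fold higher in replicate 2, and miR-124-3p, 1.74-fold higher, followed by miR-96-5p at 1.44-fold and miR-291a-3p at 1.40-fold. miR-183-5p held 0.692% of replicate 1 (95% Wilson interval 0.687 to 0.696) and 1.39% of replicate 2 (1.39 to 1.40). miR-124-3p, a neuronal miRNA, held 0.899% (0.894 to 0.905) and 1.57% (1.56 to 1.57). The liver miRNA miR-122-5p was 3.37-fold higher in replicate 2 at a mean share of 0.00177%, and miR-370-3p of the imprinted Dlk1-Dio3 region was 2.47-fold higher. Of the 427 miRNAs with at least 100 counts in each library, these last 2 and miR-183-5p, at 2.02-fold, were the 3 that differed at least 2-fold. The remaining spread was small, with 406 of the 427 within 1.5-fold and an SD of the log2 ratio of 0.30. Across the 1978 miRNAs, log2(CPM + 1) had a Pearson r of 0.997 and a Spearman rho of 0.923 between replicates; miRNAs are not independent replicates. A chi-square test of homogeneity gave a statistic of 229528 on 813 degrees of freedom, more than counting error would give if each count were an independent molecule. Fisher's exact test, two-sided with Benjamini-Hochberg adjustment, called 329 of 1212 miRNAs at an adjusted p of 0.05, which compares these libraries and not conditions. Both tests and the Wilson intervals treat counts as independent, and PCR duplicates that were not collapsed would inflate the tests and narrow the intervals.

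Grouped by genomic cluster, the miR-290/miR-295 cluster accounted for 39.1% ± 0.47 of the counts, and all 18 of its listed mature miRNAs had at least 10 counts in both libraries. Without miR-290a-5p its remaining members held 15.3% ± 0.07. The miR-17-92 cluster, which promotes proliferation, held 16.4% ± 0.48 and its paralog miR-106a/miR-363 held 13.7% ± 0.46, with the shared names miR-92a-3p and miR-19b-3p counted in both. These shared names, at 7.24% and 4.74%, made up most of the miR-106a/miR-363 sum. The smaller paralog miR-106b-25 held 1.11% ± 0.0077, and the 3 clusters together, each name counted once, held 19.3% ± 0.51. Within them, miR-20b-5p had 0.658%, miR-106a-5p 0.634%, miR-17-3p 0.551%, miR-106b-5p 0.486% and miR-18a-5p 0.479%. The difference between miR-290/miR-295 and miR-17-92 was larger than the spread between replicates. With miR-290a-5p left out of both the library total and the cluster, an alternative chosen after seeing the data, miR-17-92 stood at 21.6% and the rest of miR-290/miR-295 at 20.1%, so the lead of the cluster rested on this miRNA. In that comparison miR-17-92 kept its own most abundant member, miR-92a-3p, and the names it shares with miR-106a/miR-363. It is therefore no even ranking of the clusters.

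The miR-182/miR-96/miR-183 cluster, known from sensory organs and stem cells, held 8.35% ± 1.69, with 7.15% in replicate 1 (Wilson interval 7.13 to 7.16) and 9.54% in replicate 2 (9.53 to 9.55). The Dlk1-Dio3 imprinted region, whose miRNAs come from the maternal chromosome, held 8.05% ± 0.70, which was more than that cluster in replicate 1 and less in replicate 2, and 74 of its 84 listed names had at least 10 counts in both libraries. After miR-127-3p, its most abundant members were miR-495-3p with 0.752%, miR-665-3p with 0.680%, miR-543-3p with 0.407% and miR-376b-3p with 0.393%. The miR-15/miR-16 family, which restrains the cell cycle, held 5.49% ± 0.67, including 0.472% for miR-195a-5p. The miRNAs of the Sfmbt2 intron held 1.53% ± 0.08, led by miR-467d-3p with 0.251%. Of its 79 names, 14 share a mature sequence with another name, none of the 14 had 10 counts in either library, and the sum holds almost nothing from them. The miR-200/miR-141/miR-429 family, typical of epithelial cells, held 0.638% ± 0.03, led by miR-200b-3p with 0.237% and miR-141-3p with 0.167%.

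Lists of miRNAs that mark other cell types held small shares. The let-7 family, which rises when stem cells differentiate, made up 0.0180% ± 0.0025, and its most abundant member, let-7g-5p, stood at 0.00428%. The let-7 members differ from each other by few bases, and how reads that match several miRNAs were counted is not given in the sources used here. The miR-302/miR-367 cluster, a mark of primed pluripotency, held 0.0740% ± 0.017, most of it miR-367-3p at 0.0448%. Muscle miRNAs summed to 0.00284% ± 0.0003 and liver miRNAs to 0.0346% ± 0.001. Mesenchymal miRNAs, chosen as marks of fibroblasts or feeder cells, summed to 0.395% ± 0.002, with miR-145a-5p at 0.152% and miR-31-5p at 0.118%. In that list miR-199a-3p had 0 counts, while miR-199a-5p from the other arm of its hairpin had 632 and 1201 counts. The name miR-199a-3p shares its mature sequence with miR-199b-3p, so this 0 is not taken as a level, and the mesenchymal sum holds nothing from it. Blood miRNAs summed to 0.903% ± 0.07, of which miR-150-5p made up 0.677% and miR-142a-3p 0.108%. Neural miRNAs summed to 1.4% ± 0.47, nearly all of it miR-124-3p at 1.23% ± 0.47, while miR-9-5p stood at 0.0896%. No control pull-down of miRNAs was analysed here, so a background level could not be subtracted from these shares.

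**Figure D2:**
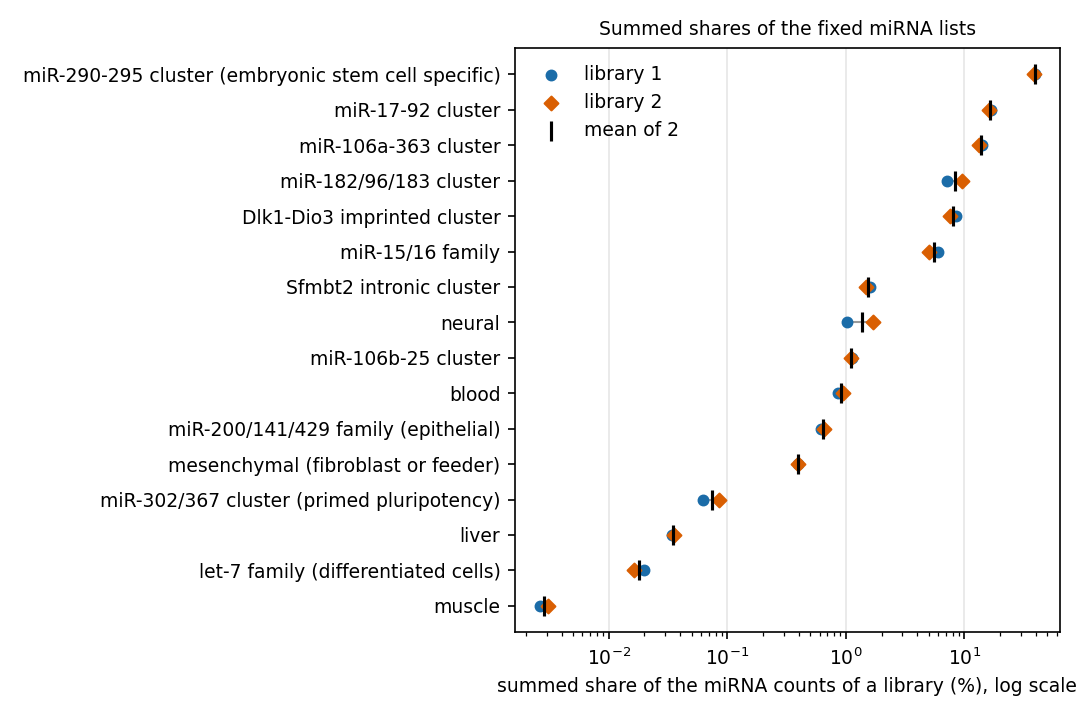
Summed share of the miRNA counts of a library (percent, log axis) for the 16 miRNA lists, with a circle for replicate 1, a diamond for replicate 2 and a bar for the mean. The miR-290/miR-295 cluster lies at 39.1% and muscle miRNAs at 0.00284%.

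Target recognition depends on the seed, nucleotides 2 to 8 of the miRNA, so counts were also summed over miRNAs with the same seed. The miR-25/miR-32/miR-92/miR-363/miR-367 family was the largest of the families fixed beforehand, with 8.24% ± 0.22. The miR-182 seed followed with 6.36% ± 0.97, the miR-19 family with 6.15% ± 0.18, the miR-291a/miR-294/miR-295/miR-302 family with 5.95% ± 0.81 and the miR-15/miR-16/miR-195/miR-497 family with 5.48% ± 0.67. The order among the miR-182, miR-19, miR-291a/miR-294/miR-295/miR-302 and miR-15/miR-16/miR-195/miR-497 families rested on differences below the spread between replicates, and each neighbouring pair of them changed order in a replicate. The miR-17/miR-20/miR-93/miR-106 family held 3.99% ± 0.12, the miR-290a/miR-292a/miR-467 family, whose seed differs from that of miR-291a-3p in its last base, 1.52% ± 0.21, and the miR-30 family 1.28% ± 0.15. The pair miR-290a-5p and miR-292a-5p, neither of them in the miR-290a/miR-292a/miR-467 family, was added as a family after the data were seen. It held 26.1% ± 0.59. This pair may not hold every miRNA with its seed, and miR-293-5p, with 6118 counts in replicate 1 and 14550 in replicate 2, was not in it. Families taken as negative controls stood at 1.23% ± 0.47 for miR-124, 0.108% ± 0.015 for miR-142-3p, 0.0896% ± 0.0012 for miR-9, 0.00177% ± 0.0014 for miR-122, 0.000347% ± 0.0001 for miR-133 and 0.000173% ± 2e-05 for miR-1/miR-206. miR-223-3p had 1 count in replicate 1 and 8 counts in replicate 2.

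Of 260 hairpins with arms paired by name and at least 100 counts in each library, 188 (72.3%) had at least 90% of their counts on 1 arm. Hairpins whose arm names differ in more than 5p or 3p were left out, among them those of miR-92a-3p, miR-19b-3p, miR-16-5p and miR-26a-5p. For 10 of these 188, an arm shares its mature sequence with another name, so its low count is not taken as a level; without these hairpins the tally was 178 of 250 (71.2%). In the miR-290/miR-295 cluster, miR-290a was almost purely 5p, with 99.96% ± 0.001 of its counts on that arm. miR-292a and miR-294 also favoured the 5p arm, with 62.3% ± 1.8 and 64.1% ± 0.80, whereas miR-293 and miR-295 favoured the 3p arm, with 5p shares of 11.1% ± 1.9 and 14.5% ± 0.88. miR-290b was almost purely 3p, with a 5p share of 0.0924% ± 0.033. The 5p arms of the cluster held 31.1% ± 1.0 of all counts and the 3p arms held 7.99% ± 0.56, a difference that rests on miR-290a-5p, since the other 5p arms held 7.31% ± 0.63. By hairpin, 6 of 9 in the cluster had more 5p than 3p counts. The major arm differed between the replicates in 2 hairpins, miR-291a and miR-142a. For miR-291a the 5p share was 60.6% in replicate 1 (Wilson interval 60.5 to 60.7) and 48.3% in replicate 2 (48.3 to 48.4), the largest difference of all hairpins at 12.2 percentage points against a median of 0.401. Outside the cluster, 122 of 251 hairpins (48.6%) had more 5p than 3p counts, and 114 of 241 (47.3%) without those that have a shared arm.

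**Figure D3:**
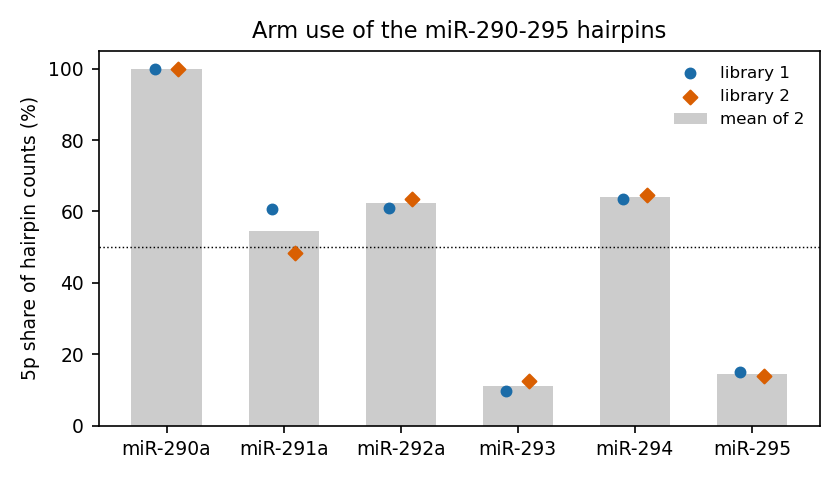
Share of 5p counts among the counts of both arms (percent) for 6 hairpins of the miR-290/miR-295 cluster, with bars for the mean of the replicates, circles for replicate 1 and diamonds for replicate 2. miR-290a lies at 99.96%, miR-293 at 11.1% and miR-295 at 14.5%, and the replicates of miR-291a fall on either side of the dotted line of equal arms.

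The target peaks asked where AGO2 may have sat on other RNAs. Whether background was removed with the input libraries is not given in the sources used here, so a peak is not shown to be an AGO2 site. The 3292 peaks, given on the mm10 build, had a median width of 58 nt with quartiles of 45 and 84 nt, and 1703 lay on the plus strand and 1589 on the minus strand. By midpoint, 3098 peaks (94.1%, exact Clopper-Pearson interval 93.2 to 94.9) lay within the span of exactly 1 protein-coding gene. A further 64 (1.94%) lay where several protein-coding genes overlap, 45 (1.37%) lay in noncoding genes or pseudogenes only, and 85 (2.58%) lay in no annotated gene. No peak overlapped a miRNA gene. The peaks within exactly 1 protein-coding gene fell in 1723 genes, of which 1114 (64.7%) had 1 such peak and 97 had at least 5. Of the 609 genes with at least 2 peaks, 608 had all of them on the same strand, the exception being Atf2. Exons, introns and untranslated regions were not used here, and the list has no value per replicate, so no replicate spread can be given for any peak.

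Peaks were concentrated toward the downstream end of genes, read in the direction of the peak strand. Over 3070 nuclear peaks in 1716 genes, the mean position was 72.5% of the way along the gene span and the median was 83.6%. The last 10% of the span held 1274 peaks (41.5%, Clopper-Pearson interval 39.7 to 43.3) and the first 10% held 109 (3.55%), an 11.7-fold difference. Within 2000 nt of the downstream end lay 1103 peaks (35.9%), against 371 expected for uniform positions and 194 within the same distance of the upstream end. In 10000 sets of uniform positions the mean was 50.01% with an SD of 0.52 percentage points, and the two-sided p was 0.0001, the smallest that many sets can give. The exact binomial test of the last against the first 10% gave a p of 2.03e-252. Uniform positions ignore that introns take up most of a gene span and that peaks of 1 gene are not independent. Genes with a single peak gave a mean of 72.1%.

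**Figure D4:**
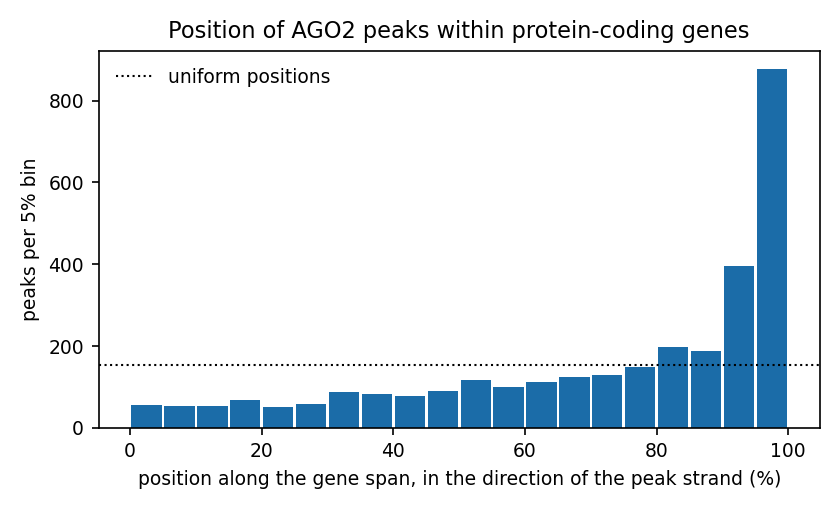
Number of peaks per bin of 5% of the gene span, read in the direction of the peak strand (horizontal axis, percent), for 3070 nuclear peaks, with a dotted line for uniform positions. The last bin holds 878 peaks and the first 55.

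The 10 genes with the most peaks included genes for matrix, transcription and chromatin proteins. Fn1, which encodes fibronectin, had 23 peaks across its span on chromosome 1 (71585473 to 71653280), of which 1 lay within 2000 nt of the downstream end. Sall1, a zinc finger transcription factor gene, had 16 peaks, 13 of them within 5000 nt of the downstream end. Srrm2, which encodes a splicing factor, had 15, and Tet1, which encodes a DNA demethylation enzyme, had 14, reaching from 288 to 75407 nt upstream of its end. Huwe1, a ubiquitin ligase gene, and Jarid2, a gene for a Polycomb partner, had 13 each. All 12 peaks of Akap12 lay within 3802 nt of its downstream end on chromosome 10 (gene span 4266329 to 4359471). Fgf4, a growth factor gene of embryonic stem cells, had 11 peaks within a span of only 3860 nt on chromosome 7 (144861386 to 144865245), 7 of them within 2000 nt of the end. Kdm5b, a histone demethylase gene, and Mga, a gene for a MYC network repressor, also had 11 each. These counts were not scaled by transcript length or abundance.

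**Figure D5:**
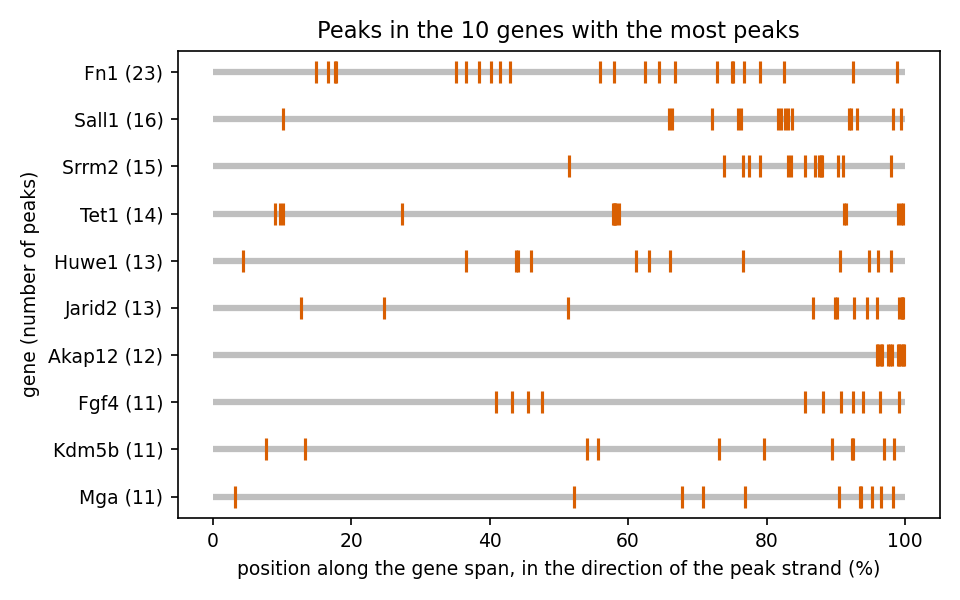
Peak midpoints (vertical ticks) along the spans of the 10 genes with the most peaks, read in the direction of the peak strand (horizontal axis, percent of the gene span), with the number of peaks in brackets. The 12 peaks of Akap12 crowd at the downstream end, while the 23 of Fn1 spread along the gene.

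Among 18 genes listed beforehand as targets of the miR-290/miR-302 family, 8 had at least 1 peak, 24 peaks in all, and each of the 8 had a peak within 2000 nt of its downstream end. In lists not chosen as targets, this held for 13 of 16 pluripotency genes with peaks, 6 of 7 chromatin genes and 1 of 5 WNT genes. Some genes are in several lists, and the difference between lists was not tested. Lefty1, an inhibitor of Nodal signalling, had 7 peaks between 19 and 511 nt from its downstream end on chromosome 1, the outermost spanning 180937852 to 180937929 and 180938366 to 180938399. Lefty2 had 1 peak, and because Lefty1 and Lefty2 are similar in sequence, the division of peaks between them is uncertain. Cdkn1a, which encodes the cell cycle inhibitor p21, had 2 peaks on chromosome 17 at 29100113 to 29100163 and 29100497 to 29100587. Ei24 had 5 peaks, Arid4b 4, the kinase gene Wee1 3, and Fbxl5 and Smarcc2 1 each. Rbl2, Lats2, Casp2, Tgfbr2, Rhoc, Mbd2, Dkk1, Nr2f2 and Irf2 were among those with none. Of 11 listed targets of miR-17-92, 4 had a peak, among them the apoptosis gene Bcl2l11 with 2, Cdkn1a with 2 and E2f3 with 1. For 3 of these 4 genes a peak lay within 2000 nt of the downstream end, whereas that of E2f3 lay 69194 nt away. Which miRNA bound at a peak was not determined, since no genome sequence was used here. No gene list was tested for enrichment, because expression in the input libraries was not analysed here, and a gene without a peak is not shown to be free of AGO2.

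Of 23 pluripotency regulators, 16 had peaks, 62 in all. After Tet1, the receptor genes Lifr and Il6st, through which LIF acts, had 9 each, and all 9 in Il6st lay between 873 and 2741 nt from the downstream end. Tet2 had 8, Klf2 5, Tfcp2l1 3, and Klf4, Esrrb, Lin28a and Tdgf1 2 each. Sox2 had 1 peak 64 nt from its downstream end on chromosome 3 (34652335 to 34652459), and Nanog had 1 peak on chromosome 6 (122711609 to 122711671). Klf5, Tbx3, Zfp42 and Stat3 also had 1 each, and Pou5f1, Prdm14, Sall4, Dppa3, Dppa5a, Utf1 and Nr0b1 had none. The pseudogenes Tdgf1-ps1 and Zfp42-ps1 had 1 peak each, so peaks of these parent genes are uncertain in their placing.

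Peaks also lay on genes of the miRNA pathway and on known let-7 targets. Of 20 pathway genes, 9 had a peak. Ago2 itself had 6, all between 26777 and 44857 nt from its downstream end, and Tnrc6a, whose protein binds Argonaute, also had 6. Tnrc6b and Tnrc6c had 3 each, Ago1, Lin28a and Trim71 2 each, and Lin28b and Tut4 1 each, while Drosha, Dgcr8 and Dicer1 had none. Of 15 let-7 targets 10 had a peak, led by Igf2bp1 with 5 and Mycn with 4, all 4 within 879 nt of the downstream end of Mycn. Only 5 of the 10 had a peak within 2000 nt of the downstream end. The nearest peak of Igf2bp1 lay 3083 nt from its end, and that of Lin28b 86747 nt. Lin28a and Trim71 had 2 each, and Lin28b, Igf2bp3, Ccnd1, Cdc25a and Nras were among those with 1, the Igf2bp3 peak also lying within another protein-coding gene, in cells where let-7 made up 0.0180% of the miRNA counts.

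In the TGF-beta, activin and BMP list 11 of 23 genes had peaks, including Ski with 4, Smad1, Smad7 and Skil with 2 each, and Nodal, Acvr1b, Acvr2b, Bmpr1a and Tgfbr1 with 1 each beside Lefty1 and Lefty2. Of 27 genes of G1/S control 11 had peaks, among them Cdk4 with 2 and Cdkn1b, Ccne1, Ccne2, E2f4 and Lats1 with 1 each, though the Ccne2 peak also lay within another protein-coding gene. The chromatin and DNA methylation list had 48 peaks in 7 of 21 genes, with 5 in Dnmt1, 3 in Suz12 and 1 in Kdm6b beside Tet1, Jarid2, Tet2 and Arid4b. Among 17 apoptosis genes 6 had peaks, with 4 in Mcl1, 3 each in Trp53 and Trp53inp1 and 1 in Bcl2l1 beside Ei24 and Bcl2l11. Of 12 WNT genes 5 had peaks, with 7 in Ctnnb1, the gene for beta-catenin, 5 in Tcf7l1, 3 each in Apc and Lrp6 and 1 in Gsk3b. In the PI3K, AKT and mTOR list 4 of 14 genes had peaks, among them Rictor and Foxo1 with 1 each. None of the 12 germ layer and trophectoderm markers had a peak. Over all 21900 annotated protein-coding genes, 1723 had a peak that lay in no other such gene. At that rate a list of 12 genes could lack peaks without any special property, so the result does not set these markers apart. Of 9 fibroblast markers Fn1 alone had peaks. Over all 13 lists, 74 of 191 different genes had a peak, and 41 had at least 2. No list count was tested against that of all protein-coding genes, because expression was not analysed here.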

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

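A miRNA share counted as moved when it changed by at least its SD between replicates, however small, a count of genes when it changed by more than 1.5-fold, and the share of peaks in 1 gene when it left its 95% interval. Of 560 alternative values for 143 results, 120 came from a factor per library and 252 from 1 replicate alone. The former leave shares relative to each other within a library as they are, and a share from 1 of 2 replicates lies within 1 SD of their mean by construction, so neither tests stability. Of the other 188, 164 stayed within the tolerance and 24 moved. Of these 164, 124 came from the minimum of 10 counts in each library. That minimum hardly changes a library total, so these 124 say little about stability either. The 20 most abundant miRNAs held 71.2275% without it and 71.2355% with it. The mean position of peaks stayed in the downstream part of genes in each alternative. Settings planned before the data were examined were TMM and DESeq2 scaling, the count minimums, the pseudocount, the seed definition, midpoint against overlap for peak locations and each replicate alone; the rest were chosen after seeing the data. The correlation between replicates ran from 0.995 to 0.998, the share of peaks in 1 protein-coding gene stayed at 94.1%, and the mean position ran from 72.1% to 73.3%, each at p = 0.0001. With miR-290a-5p left out of the total and of every sum that held it, the rest of the top 20 held 62.2% and the rest of miR-290/miR-295 20.1%, both lower because they lost this member. The smaller total alone raised miR-17-92, which kept its own most abundant member, to 21.6%, above the rest of miR-290/miR-295. The smaller total also raised the miR-291a/miR-294/miR-295/miR-302 family to 7.80%. The major arm of 2 hairpins differed between the replicates. In a replicate alone, 11 of 19 neighbouring pairs among the 20 most abundant miRNAs changed order, as did 3 of 15 pairs of lists and 21 of 47 pairs of seed families. A seed of nucleotides 2 to 7, which merges the miR-291a/miR-294/miR-295/miR-302 and miR-290a/miR-292a/miR-467 families, gave 7.47%. The share of hairpins with 90% of counts on 1 arm was 68.8% at a minimum of 20 counts, 75% at 1000, 72.7% to 73.1% with each replicate alone, and 71.2% without hairpins that have an arm sharing its sequence with another name; the cause was not tested. Requiring 2 peaks per gene left 41 of 74 listed genes, since fewer genes pass by construction. No paired analysis was possible because only the miRNA group has values per library. Not run were seed matches in peaks and all their alternatives, peaks split by strand of the gene, 3' untranslated regions and their length minimum, and the stronger part of the peaks by score. Depth limits shares to above 2.39e-05% in replicate 1 and 1.31e-05% in replicate 2.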

Other observations

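All tests in this part were chosen after the results were seen. Several RNAs outside the gene lists carried peaks. The long noncoding RNA Rian of the Dlk1-Dio3 region had 6 peaks and its neighbour Meg3 had 2, all 1145 to 31737 nt from the nearest annotated miRNA gene. Lncenc1, a noncoding RNA of embryonic stem cells, had 5 peaks, Snhg1 3, Tug1 2 and Malat1 1, and 2 lay in each of the overlapping genes Xist and Tsix. Of 84 ribosomal protein genes, taken by symbol, 56 had a peak. Their 119 peaks had a median position of 54.4% along the gene span, with 12.6% in the last 10%, against 41.5% over all nuclear peaks; the difference was not tested, and many of these genes have pseudogenes.

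The mitochondrial genome carried 29 peaks, all on the plus strand. Of the peaks within exactly 1 protein-coding gene, ND5 had 9, ND1 and ND4 5 each, ND2 and CYTB 3 each, ND6 2 and COX1 1. ND6 is encoded on the opposite strand to the other protein-coding genes, so both peaks within its span lay antisense to it. Peaks fell within the spans of 7 of 13 protein-coding genes and of 0 of 2 ribosomal RNA genes and 0 of 22 transfer RNA genes. Among nuclear protein-coding genes outside the lists and the 10 with the most peaks, Lamp2, Nedd4, Nsd1 and Prrc2a had 10 peaks each, and Lmtk2, Tnks2 and Tns3 9 each.

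Names that share a mature sequence had almost no counts. Of 16 such names in 7 sets, taken from known sequences and not exhaustive, 0 had 10 counts in either library, and they held 1 count in replicate 1 and 0 in replicate 2. In the Sfmbt2 cluster 0 of 14 such names reached 10 counts, against 61 of 65 other names. Reads matching several mature miRNAs may not have been counted, in which case these zeros say nothing about the cells. That explanation was drawn from these same counts, so they are no test of it, and it stays open, as does low expression of these miRNAs. No biological explanation was tested.

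miR-124-3p, at 1.23% of the counts, stood apart from the other neural miRNAs. The hypothesis that RNA from neural cells is the source was set against miR-9-5p, miR-128-3p, miR-132-3p, miR-137-3p and miR-219a-5p, whose median was 1.16% of the level of miR-124-3p. miR-9-5p, the highest of them, reached 7.27%. The ratio of replicate 2 to replicate 1 was 1.74 for miR-124-3p, against 1.02 for miR-9-5p, 1.01 for miR-219a-5p and 0.876 for miR-128-3p. For miR-132-3p it was 1.35, from 41 and 101 counts, and for miR-137-3p 0.465, from 33 and 28 counts, too few to weigh. These values argue only against neural RNA that carries the other miRNAs in amounts comparable to miR-124-3p. Levels in neural cells were not used here for comparison, and a source with miR-124-3p nearly alone stays open. Carry-over between libraries and expression in the stem cells themselves were not tested.

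The 5p arms held most of the miR-290/miR-295 counts, which a general excess of 5p reads in these libraries could produce. The excess rested on miR-290a-5p, since the other 5p arms held 7.31% of all counts and the 3p arms 7.99%. Outside the cluster 48.6% of the 251 hairpins with arms paired by name had more 5p than 3p counts. Inside the cluster miR-290b, miR-293 and miR-295 favoured the 3p arm. More 5p than 3p counts was therefore not the rule among the paired hairpins. This tally cannot decide whether 5p reads were favoured in general. Of 260 paired hairpins, 188 had at least 90% of their counts on a single arm, where a moderate bias would seldom change the leading arm. The tally to be found without a bias was not known either, so a general excess of 5p reads stays open. A ligation bias toward single sequences such as miR-290a-5p was not tested and stays open, as does a true difference in arm loading.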
